A study of Mus musculus with 4 samples.

How the data were processed

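The series holds single-cell RNA sequencing of a mouse soft-tissue sarcoma grown in 6 recipient mice. Per the labels, the tumor cells are mesenchymal stem cells that were transformed by loss of p53 and overexpression of cyclin E1 (Ccne1), and they were placed under the skin on polyurethane scaffolds. Tumors were taken at about 1 cm3, digested to single cells, enriched in part for cells with CD45 (the surface marker of blood-derived cells), marked with 1 of 6 hashtag antibodies per tumor, pooled, and loaded on 2 captures of a 10x Genomics 3' RNA kit, also per the labels. The labels give every tumor the same treatment, so the 6 tumors form 1 group and every comparison is between cell classes of the same tumors or between the 2 captures of the pool. Cells are not replicates, and the tumor is the replicate in each test.

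The deposited matrices hold raw UMI counts per feature and cell barcode, 1 matrix per capture, with 31055 gene features, 5 antibody features and 8 hashtag features. Per the submitters' processing notes, Cell Ranger, the mouse genome build mm10 and Seurat 4 were used, and the notes give no order of steps. A deposited table lists barcodes with the authors' call of their mouse, and how the hashtags were called is not stated. The leading hashtag of 7041 called barcodes was the one of their own mouse, and that of 5 was another. The matrices held 11119 barcodes (6079 in capture 1 and 5040 in capture 2), of which the authors called a single mouse for 7046. The design aimed at about 10000 cells in all. The table names no doublets or negatives and gives no reason for a missing call. The 4073 barcodes without one were left out of every comparison.

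Called barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept. The mitochondrial limit removed 95, which left 6951 cells (3689 and 3262) with 94423968 UMIs. The median cell had 11096 UMIs and 3083 genes. No doublet call was made beyond the authors' mouse calls, and hashtags cannot see doublets within a tumor. Scrublet's automatic threshold marked 2 barcodes of 5649 in capture 1 and 4 of 4624 in capture 2, so it did not work here and its calls were not used. Leaving out the 348 cells with the highest Scrublet scores was added as an alternative after the data were examined.

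Counts per cell were scaled to 10000 and log-transformed in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1). Every gene of the fixed lists, mitochondrial genes and ribosomal genes were removed before the 2000 most variable genes were chosen, so that list genes could be tested between clusters. Other genes that vary together with list genes stayed in and could shape the clusters. A list test between clusters therefore describes them and is no independent evidence. Clusters came from 30 principal components (scikit-learn 1.9.0), 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1, with both captures together. Markers of 20 cell types were fixed before the data were examined. The scoring rule was not. A type needed at least 3 of its markers seen in 25% of a cluster's cells and a mean z of its markers of at least 0.5. Among types within 90% of the best z, the one with most markers among the cluster's 10 leading genes gave the name. A cluster whose first gene marks another type, whose leading genes hold more markers of another type, or whose cells are shallow with no own marker among those genes stayed unnamed. Monocytes and macrophages were treated as 1 family. Within it a cluster is monocyte-like where the monocyte markers have the higher mean z and that z is above 0.5, and macrophage-like otherwise, which was also settled after the data were seen. Clusters 2 (z of -0.038 for monocyte and -0.138 for macrophage markers) and 4 (-0.069 and -0.347) have the higher monocyte z and are macrophage-like by the minimum alone, so counting both as monocyte-like was added as an alternative after the data were examined. All names mean "like" that type, since the deposited tables give no cell types.

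For each comparison, raw counts were summed per tumor and cell class over both captures, using tumors with at least 10 cells of each class. Genes were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): TMM scaling, the filterByExpr filter, and a quasi-likelihood test with the tumor as a block. A gene is called higher or lower with a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Counts of called genes leave out the genes used for clustering, which made the clusters. The sums pair by design, because both come from the same animal. Deviations of same-numbered sums from their class means correlated at -0.011 to 0.103 for sarcoma-like against monocyte and macrophage-like cells, at 0.095 to 0.389 for monocyte-like against macrophage-like cells, and between captures at 0.077 to 0.44 in sarcoma-like and 0.333 to 0.654 in monocyte and macrophage-like cells. In the first of these, the highest correlation with another tumor was 0.028 to 0.124 and mostly exceeded that of the same tumor. The data therefore show little pairing there. In the others the same tumor always correlated highest.

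The 21 gene lists hold 245 genes, of which 1 has no feature. They were fixed before the data were examined and cover MIF ligands and receptors, CC chemokines, CXC and CX3C chemokines, cytokines, growth factors, glycolysis, hypoxia response, alternative activation and tissue residence of macrophages, lipid-associated macrophage genes, pro-inflammatory activation, interferon response, MHC class I and MHC class II presentation, checkpoint genes, complement, cell cycle, p53 targets, extracellular matrix remodelling, dissociation stress, engineered genes and sex-linked genes. Lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Genes named in the text are the members of the MIF list and, of each other list, up to 3 members with the largest absolute fold change among those called and changed the same way in every tumor. A list with no such member gives its most abundant gene. Up to 5 more per direction are the genes with the largest fold outside the clustering genes and the marker lists, with a mean log2 CPM of at least 5. Fewer were printed in the order of that rule. No fold is given for a gene at 3 or fewer counts in a class.

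Single genes were compared between classes as log2(CPM + 1) per tumor with an exact two-sided sign-flip test over the 64 sign choices of 6 tumors, whose smallest p is 0.03125. Benjamini-Hochberg adjustment ran over 35 tests of MIF genes and over 40 tests of engineered and sex-linked genes. Relations across tumors used Pearson's r and Spearman's rho with exact p over all 720 pairings. Positions of genes come from the RefSeq annotation of GRCm38.p6, the assembly behind mm10, matched by symbol for 11368 of 11511 tested genes.

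The test was run on simulated counts with 200 changed genes before it was run on the data. For sarcoma-like against monocyte and macrophage-like cells, with 11304 genes tested, all 100 genes changed 4-fold and 96 of 100 changed 2-fold reached an adjusted p under 0.05, and the fold threshold left 42 of the latter. The alternatives were other scaling (no TMM, DESeq2 1.42.0), no filter on low counts, no tumor block, 1 capture or 5 tumors only, no minimum fold, all tested genes, Leiden resolution 0.5 or 2, clusters made on 1 random part of the UMIs and genes tested on the rest, at most 10% mitochondrial UMIs with at least 500 genes, and a pseudocount of 10. Antibody counts entered no test. The raw reads were not used.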

Results

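Single-cell RNA was collected from 6 mouse sarcomas, each grown from the same transplanted cells in its own recipient mouse, and from their infiltrating cells after partial enrichment for CD45. After filtering, 6951 cells with a tumor of origin were compared. Tumors 1 to 6 gave 1509, 1232, 1227, 982, 926 and 1075 cells with 24448566, 17272996, 19259951, 10544258, 9851635 and 13046562 UMIs. The median depth was 10590 UMIs per cell in capture 1 and 11601 in capture 2. The labels name no second treatment group, so tumors are not compared with each other by a test.

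Macrophage-like cells made up most of the suspension, at 64.7% ± 6.02 (SD, n = 6 tumors) of analysed cells, with tumors between 56.9% and 70.9%. Monocyte-like cells followed at 9.73% ± 5.05, and sarcoma-like cells, named from collagen and other mesenchymal genes, at 9.33% ± 4.27. Neutrophil-like cells made up 3.71% ± 3.33, type 2 conventional dendritic-like cells 2.79% ± 0.697, and T-like cells 2.18% ± 0.955. NK-like cells (0.757% ± 0.460), migratory dendritic-like cells (0.587% ± 0.292), host fibroblast-like cells (0.436% ± 0.0959) and endothelial-like cells (0.265% ± 0.245) were rarer. The CD45 enrichment sets these shares in part. Of all cells other than sarcoma-like, fibroblast-like and endothelial-like ones, 83.0% ± 6.65 were monocyte-like or macrophage-like. The 21 clusters included 6 that were macrophage-like (clusters 1, 2, 3, 4, 10 and 12), 2 that were monocyte-like (5 and 14) and 4 that were sarcoma-like (7, 9, 15 and 20). Cluster 6, with 331 cells led by Ighm, the heavy chain of IgM, which varied widely between tumors (1382 ± 3228 CPM) and which also held C1qa (3272 ± 873 CPM), and cluster 18, with 30 cells led by Ctsk and Acp5, genes of bone-resorbing cells, stayed unnamed. They made up 5.50% ± 2.56 of cells together. With cluster 5 counted as macrophage-like, the macrophage-like share was 72.6% and the monocyte-like share 1.86%, and with clusters 2 and 4 counted as monocyte-like, the shares were 35.7% and 38.7%.

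**Figure D1:**
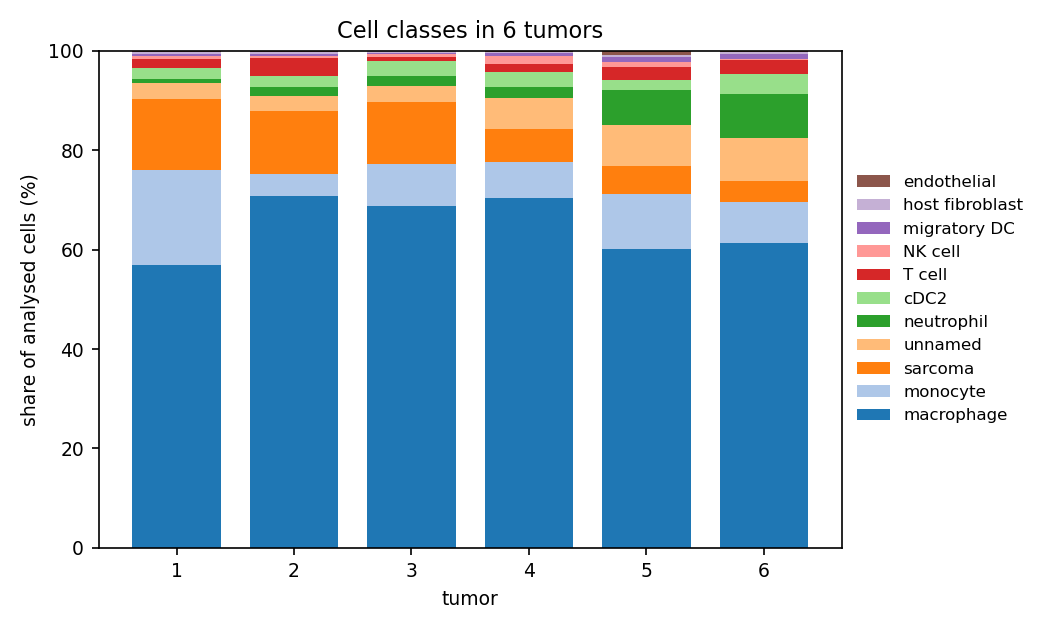
Share of analysed cells (%) in each cell class, as 1 stacked bar per tumor. Macrophage-like cells take between 56.9% and 70.9% of every tumor, and sarcoma-like cells between 4.28% and 14.3%.

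The series title names tumor-expressed MIF, macrophage migration inhibitory factor, so the first comparison asks which cells hold its RNA and that of its receptors. Mif RNA was present in all classes compared and was highest in sarcoma-like cells, at 909 ± 158 CPM (SD, n = 6 tumors), against 634 ± 57.8 in macrophage-like cells, a log2 difference of 0.506 ± 0.294 (higher in 6 of 6 tumors). CPM are shares of the UMIs of a class and do not give RNA per cell. Sarcoma-like cells had a median of 31789.5 UMIs, macrophage-like cells 11348, monocyte-like cells 7634 and neutrophil-like cells 1457. The sarcoma-like clusters differed, with 658 ± 110 CPM in cluster 7, the largest with 327 of 688 cells, 930 ± 52.97 in cluster 9 and 1721 over all cells of cluster 15. The receptor chain Cd74, which is also the invariant chain of MHC class II, showed the opposite order. It stood at 76.5 ± 59.1 CPM in sarcoma-like cells, at 5140 ± 2030 in macrophage-like cells and at 27663 ± 1361 in type 2 conventional dendritic-like cells. Mif averaged 502 ± 113 CPM in monocyte-like, 457 ± 150 in neutrophil-like, 415 ± 74.0 in dendritic-like and 376 ± 159 in T-like cells, with log2 differences of 0.877, 1.05, 1.13 and 1.37 from the sarcoma-like class. The Mif homolog Ddt stood at 73.2 ± 3.03 CPM in sarcoma-like and 60.4 ± 1.55 in macrophage-like cells (log2 difference 0.273, higher in 6 of 6 tumors). Cd44, a partner of Cd74 at the cell surface, was lower in sarcoma-like (168 ± 24.1 CPM) than in macrophage-like cells (433 ± 71.7 CPM) by a log2 difference of -1.36. The chemokine receptor Cxcr4 stood at 2.48 ± 1.37 against 172 CPM (-5.77), and the atypical receptor Ackr3 at 15.8 ± 6.20 against 4.57 ± 0.969 CPM (1.53). Cxcr2, another receptor of MIF, was found mainly in neutrophil-like cells, at 663 ± 198 CPM, and had 5 counts in sarcoma-like cells. Cd74 in sarcoma-like cells lay at 1.51% of the macrophage-like level and Cxcr4 at 1.65%, where Ptprc, the gene of CD45, lay at 0.872% and C1qa at 0.858%. The T-like class also held macrophage RNA, with C1qa at 1959 CPM over all its cells against 4138 in macrophage-like cells. This bears on its Cd74 level of 6078 CPM and on its Mif values. Dendritic-like cells held C1qa at 742 CPM.

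Mif in sarcoma-like cells against the 5 other classes reached the smallest exact two-sided p that 6 tumors allow, 0.03125 (adjusted p = 0.0421 over 35 tests, same direction in 6 of 6 tumors). So did Cd74 against each class, with log2 differences of -6.41 (macrophage-like), -6.96 (monocyte-like), -2.52 (neutrophil-like), -8.92 (dendritic-like) and -6.64 (T-like). With cluster 7 alone as the sarcoma-like class, Mif did not pass against macrophage-like (0.042, exact adjusted p = 0.8286), monocyte-like (0.412, exact adjusted p = 0.122) or T-like cells (0.908, exact adjusted p = 0.0841). Cd74 did not pass against neutrophil-like cells there (-2.74, exact adjusted p = 0.0841). With cluster 9 alone Mif passed against all 5 (0.555 against macrophage-like cells). Ddt did not pass against monocyte-like, dendritic-like and T-like cells (exact adjusted p = 0.292, 0.423 and 0.497), and Cd44 did not pass against dendritic-like cells, which held 215 CPM (exact adjusted p = 0.226). Leaving out 1 tumor gave 0.414 (without tumor 1) to 0.575 (without tumor 4) for Mif against macrophage-like cells. The exact test cannot pass with 5 tumors. At the smallest p, how many other tests reach it sets the adjusted p, so a miss alone shows no loss. Mif and Cd74 against macrophage-like cells did not pass in 1 capture alone. They stood at 0.461 and -6.25 without capture 1 (exact adjusted p = 0.0875 each). Without capture 2 they stood at 0.535 and -7.30 (exact adjusted p = 0.0684 each). Counting cluster 5 as macrophage-like gave 0.526 for Mif (exact adjusted p = 0.0521). Mif passed with clusters 2 and 4 counted as monocyte-like (0.799) and without clusters 15 and 20 (0.357).

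**Figure D2:**
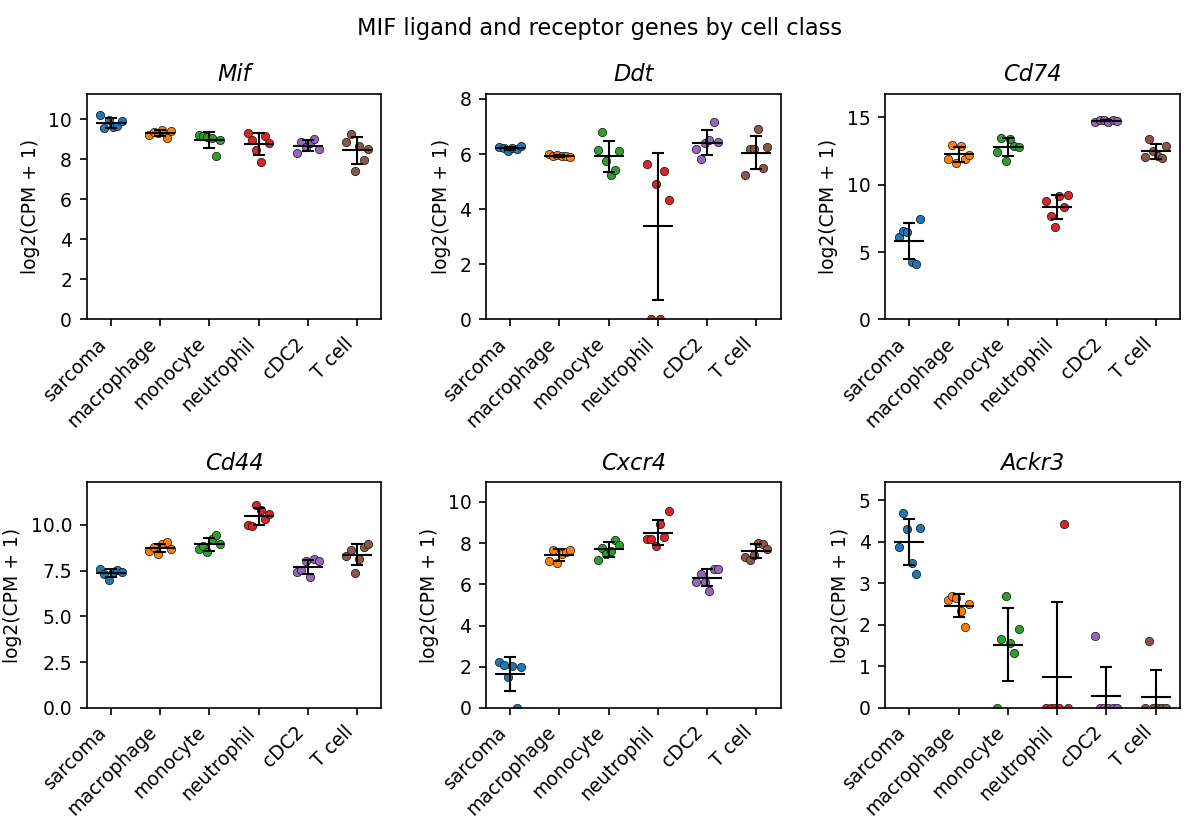
Expression in log2(CPM + 1) of Mif, Ddt, Cd74, Cd44, Cxcr4 and Ackr3 by cell class, 1 panel per gene, with points for the 6 tumors and bars for the mean ± SD. Mean Mif is highest in sarcoma-like cells (909 CPM) and mean Cd74 in type 2 conventional dendritic-like cells (27663 CPM).

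Mif (ENSMUSG00000033307) is a protein-coding gene on chromosome 10 of mm10 (75859353 to 75860277), with Ddt on the same chromosome (75771233 to 75773374). Cd74 (ENSMUSG00000024610) is on chromosome 18 (60803849 to 60812652), Cd44 on chromosome 2 (102811141 to 102901669), and Cxcr4 (128588199 to 128592299) and Ackr3 (90203980 to 90215724) are both on chromosome 1.

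Engineered and sex-linked genes were compared between sarcoma-like and macrophage-like cells to ask which class holds the transplant. Y-linked RNA was scarce in the sarcoma-like class. Ddx3y (chromosome Y, 1260715 to 1286628) stood at 1.24 CPM against 101, Eif2s3y at 0.388 against 50.2, Uty at 0.425 against 33.4 and Kdm5d at 0.190 against 11.0, with log2 differences of -5.58, -5.24, -4.62 and -3.35, lower in 6 of 6 tumors. Xist, the RNA that coats an inactive X chromosome (chromosome X, 103460373 to 103483233), had 3 counts in sarcoma-like and 1 in macrophage-like cells. Ccne1 (ENSMUSG00000002068, chromosome 7, 38097984 to 38107490), the overexpressed cyclin, stood at 14.2 ± 4.79 CPM in sarcoma-like and 16.1 ± 3.05 in macrophage-like cells (log2 difference -0.209, exact two-sided p = 0.4375, adjusted p = 0.603 over 40 tests, higher in 2 of 6 tumors). Trp53 (ENSMUSG00000059552, chromosome 11, 69580348 to 69591873), the gene of p53, stood at 136 ± 15.1 against 65.2 ± 4.61 CPM (1.05, higher in 6 of 6 tumors). A 3' tag can lie outside the deleted part of Trp53 or outside an added Ccne1 copy, so neither value checks the labels. Trp53 and the 4 Y-linked genes each had the smallest exact two-sided p, 0.03125. Their adjusted p of 0.0625, set by how many other tests reach 0.03125, does not pass.

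Sarcoma-like cells differed from the pooled monocyte-like and macrophage-like cells of the same tumors in 4209 of 10395 genes, 2030 of them higher and 2179 lower. Tenm3, a cell adhesion protein of the teneurin family, stood at 121 against 0.392 CPM (log2 fold change 7.98 ± 0.171 SE, edgeR adjusted p = 1.55e-12, higher in 6 of 6 tumors). The matrix protein Tnc (7.54, 263 against 1.25 CPM), the protease inhibitor Timp3 (7.19), the collagen cross-linking enzyme Loxl2 (7.06) and the collagen gene Col16a1 (7.56) were higher as well. The transglutaminase gene F13a1 was lower at -8.07 ± 0.199. Mif itself stood at 909 ± 158 against 623 ± 62.8 CPM (log2 fold change 0.34 ± 0.102 SE, edgeR adjusted p = 0.00828, 6 of 6 tumors), which is under the minimum fold, and at 0.198 without clusters 15 and 20, of which cluster 15 comes mostly from tumor 1. Of the MIF ligands and receptors, Ackr3 was higher (1.65), Cd74 (-6.50 ± 0.473), Cd44 (-1.58) and Cxcr4 (-6.16) were lower, and Ddt stood at 0.08.

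Secreted factors split between the classes. Cxcl12, which draws cells that carry Cxcr4, was higher in sarcoma-like cells at 198 against 1.57 CPM (6.73 ± 0.123), while Pf4 (-7.84) and Cxcl3 (-7.90) were lower, among 2 higher and 6 lower of 10 CXC and CX3C chemokines (camera adjusted p = 0.307). Of 9 CC chemokines 7 were lower, led by Ccl6 (-7.46) and Ccl9 (-7.04) (camera adjusted p = 0.000569). That call was lost at an adjusted p = 0.205 with an estimated correlation. Cytokines were lower in 9 of 10, including Il1b (-6.84), its antagonist Il1rn (-6.74) and Osm (-6.43) (camera adjusted p = 0.000278, adjusted p = 0.307 with an estimated correlation). Growth factors went both ways, with 7 higher and 5 lower of 17 (camera adjusted p = 0.254): Tgfb2 (7.12) and the lymphatic growth factor Vegfc (6.46) were higher, and Gas6 (-8.01) and Vegfa (-2.47) were lower. The extracellular matrix list had 9 higher and 5 lower of 15 and a median log2 fold change of 3.53 (camera adjusted p = 0.000569, adjusted p = 0.307 with an estimated correlation).

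Immune lists were lower by camera at its preset correlation. All 7 genes of alternative activation and tissue residence of macrophages, such as Arg1 (-7.80), had a median of -7.21 (camera adjusted p = 6.28e-08, adjusted p = 0.278 with an estimated correlation). All 7 MHC class II genes, among them Ctss (-7.03) and H2-DMa (-6.58), had a median of -5.96 (camera adjusted p = 0.000275, adjusted p = 0.307 with an estimated correlation). Checkpoint genes were lower in 10 of 11, with Cd86 at -6.87 and Sirpa at -6.49 (camera adjusted p = 9.51e-07, adjusted p = 0.205 with an estimated correlation), and all 6 complement genes were lower, with the receptors C5ar1 at -7.08 and C3ar1 at -7.02 (camera adjusted p = 1.61e-05, adjusted p = 0.288 with an estimated correlation). Lipid-associated macrophage genes were lower in 10 of 15 (Abcg1 -7.25, Trem2 -7.13; camera adjusted p = 4.48e-05) and pro-inflammatory genes in 8 of 10 (Nlrp3 -6.89; camera adjusted p = 4.48e-05), at an adjusted p = 0.307 and 0.288 with an estimated correlation. The interferon response was lower in 12 of 16 (Rsad2 -3.43, Irf7 -3.42; camera adjusted p = 0.0349) and MHC class I presentation in 5 of 10 (Psmb9 -3.16, Psmb8 -2.18; camera adjusted p = 0.0234), at an adjusted p = 0.550 and 0.399 with an estimated correlation. The 4 sex-linked genes tested were lower (Eif2s3y -6.93, Ddx3y -6.73; camera adjusted p = 0.000233, adjusted p = 0.307 with an estimated correlation).

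Among lists with no call, cell cycle genes had 2 of 20 higher, Cenpf (1.16) and Ccnb1 (1.12), and a median of 0.52 (camera adjusted p = 0.507). Cycling cluster 3 raises this reference, so a larger rise may be hidden. The p53 targets had 3 higher and 6 lower of 12 (camera adjusted p = 0.507), with the cell cycle inhibitor Cdkn1a at -5.02 and Phlda3 at 4.18. Glycolysis had 4 of 16 lower, led by the lactate exporter Slc16a3 at -6.46 (camera adjusted p = 0.152), the hypoxia response 2 higher and 2 lower of 12 (camera adjusted p = 0.600), dissociation stress 2 higher and 3 lower of 11, with Jun at 1.90 and Hspa1a at -5.83 (camera adjusted p = 0.734), and the MIF list 1 higher and 3 lower of 6 (camera adjusted p = 0.254). Neither engineered gene was called, with Trp53 at 0.88, and that list is too short for camera. Adjusting over the list alone changed no list count of this comparison. Without TMM the median of all genes moved from -0.01 to 0.188 and Trp53 passed at 1.08. Cenpf lost its call without tumor 5 (0.86) or capture 1 (0.90), and Ccnb1 without tumor 2 (0.98) or tumor 5 (0.82).

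Monocyte-like cells had higher interferon-induced genes than macrophage-like cells, and 588 of the 707 monocyte-like cells are cluster 5, whose leading genes are such genes. The result therefore describes cluster 5 more than monocytes. The monocyte-like class also held macrophage RNA, with C1qa at 3705 and Csf1r at 543 CPM over all its cells. Macrophage-like cells held 4138 and 591 CPM. With cluster 5 counted as macrophage-like the sign turns, with Ifit3 at -2.91. All 16 interferon response genes tested were higher, with a median log2 fold change of 3.93, led by Ifit3 (5.76 ± 0.145 SE, 371 against 7.18 CPM, edgeR adjusted p = 1.67e-16, 6 of 6 tumors), Ifit1 (5.07) and Ifit2 (4.95). Proliferation genes were lower, with 12 of 20 cell cycle genes including Ccna2 (-3.47), Cenpf (-3.30) and Mki67 (-2.92), and a median of -1.70. The macrophage-like sum includes the cycling cluster 3, with 744 of 4482 cells, so the fall cannot be told apart from a raised reference. In all 177 genes were higher and 272 lower of 9073. Mif stood at 502 CPM in monocyte-like and 634 CPM in macrophage-like cells (-0.25 ± 0.088, edgeR adjusted p = 0.0386, lower in 6 of 6 tumors), under the minimum fold.

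Of the chemokines, Cxcl10 (3.60, 879 against 75.5 CPM), Ccl5 (2.82) and Ccl12 (1.53) were higher, and Cxcl3 (-2.69) and Pf4 (-1.60) were lower. The CC list had 2 of 10 higher (camera adjusted p = 0.00966, adjusted p = 0.194 with an estimated correlation), and the CXC and CX3C list 2 higher and 3 lower of 8 (camera adjusted p = 0.639). Of 10 cytokines 5 were higher, among them Il15 (1.93), Il18 (1.27) and Il1b (1.11) (camera adjusted p = 8.67e-05, adjusted p = 0.0356 with an estimated correlation). The pro-inflammatory list had 3 higher and 1 lower of 10, with the costimulatory receptor Cd40 at 2.00 and Acod1, the itaconate-making enzyme, at 1.55 (camera adjusted p = 0.000247). MHC class I presentation had 3 of 10 higher, including its transactivator Nlrc5 (1.77) and the peptide transporter Tap1 (1.26) (camera adjusted p = 5.09e-19). Complement genes C3 (1.23) and Cfb (1.61) were higher (camera adjusted p = 0.0679, 2 of 7). Also lower were Cbr2 (-2.48) and Folr2 (-1.17) of the alternative activation list (2 of 7, camera adjusted p = 3.58e-06), Cd36 (-3.47), Ctsl (-1.28) and Spp1 (-1.28) of the lipid-associated list (7 of 15, camera adjusted p = 6.91e-07, adjusted p = 0.247 with an estimated correlation), the growth factor Igf1 (-3.52) and the elastase Mmp12 (-3.09). MHC class II genes, with no member called, had a median of 0.65 with Cd74 at 0.65 (camera adjusted p = 1.49e-05, adjusted p = 0.111 with an estimated correlation), and checkpoint genes, also with none called, a camera adjusted p of 0.00189 (adjusted p = 0.221 with an estimated correlation). Dissociation stress genes had no call and a median of 0.44, with Junb at 0.51 (camera adjusted p = 7.73e-06). The calls that held with an estimated correlation were the interferon response (adjusted p = 0.00285 with an estimated correlation), MHC class I, cell cycle and dissociation stress (each 0.0213), alternative activation and pro-inflammatory activation (each 0.0332), and cytokines. Of the MIF list, Cd44 (0.30), Cxcr4 (0.37), Ddt (0.14) and Ackr3 (-1.27, adjusted p = 0.0751) were not called. Adjusted over the list alone, Ackr3 passed.

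With cluster 5 counted as macrophage-like, the monocyte-like class is cluster 14 alone, tested in 5 tumors because tumor 2 had 7 of its cells. There 731 genes were lower, and Ifit3 (-2.91), Ifit1 (-1.98), Ifit2 (-1.87), Rsad2 (-1.41), Cxcl10 (-1.18), Ccl12 (-2.91), Il15 (-2.58), Cd40 (-0.85) and Ccl5 (-0.50) turned to the lower side. So did the interferon, CC chemokine and MHC class II lists, without a call (camera adjusted p = 0.376, 0.144 and 0.148), and the calls of checkpoint and dissociation stress genes were lost (camera adjusted p = 0.0553 and 0.0778). Spp1 (-0.87), Acod1 (0.37), Nlrc5 (0.68), Tap1 (0.47) and Cfb (0.25) lost their calls there, and Cd44 (1.10) and Cxcr4 (1.01) passed. At Leiden resolution 2 Mif (0.38), Ackr3 (1.64), Cxcl3 (3.70), Cd36 (0.39), Spp1 (0.70) and Mmp12 (0.53) turned to the higher side, and Ccl12 (0.50), Pf4 (-0.55), Il18 (0.83), Tap1 (0.69) and Ctsl (-0.24) lost their calls. Clusters 2 and 4, counted as macrophage-like, have a higher mean z of monocyte than of macrophage markers, and cluster 2 has the monocyte gene Ccr2 and no macrophage marker among its 10 leading genes. With both counted as monocyte-like, 157 genes were higher and 361 lower, Ifit3 stayed higher, and Mif (0.66), Ackr3 (2.18), Cxcl3 (4.33), Cd36 (3.23), Mmp12 (3.57), Spp1 (2.73), Ctsl (1.46) and Igf1 (0.83) turned to the higher and Ccl12 (-0.49), Il18 (-0.038) and Tap1 (-0.043) to the lower side. Cxcl10 (0.85), Pf4 (-0.03), Il15 (0.13), Cd40 (0.14), Nlrc5 (0.50) and Cfb (0.50) lost their calls and Cd74 passed (1.09). The lipid-associated list turned to the higher side (camera adjusted p = 4.5e-08). MIF, CXC and CX3C chemokine, glycolysis, hypoxia and matrix lists were called higher (camera adjusted p from 2.8e-07 to 0.00203). The calls of CC chemokines, alternative activation, MHC class I and dissociation stress were lost (camera adjusted p = 0.359, 0.207, 0.122 and 0.963). Some calls lay under the minimum fold in part of the data: Il18 stood at 0.96 without capture 1, Folr2 at -0.82 and C3 at 0.96 without capture 2, Il1b at 0.98 and Ctsl at -0.998 without tumor 5, Il1b at 0.97 and C3 at 0.99 with the stricter cell filter, and Ccl12 at 0.99 on separate UMIs, where the CC list was lost (camera adjusted p = 0.480). Ackr3 passed at -2.07 without tumor 3, -1.37 without TMM, -1.32 without the filter on low counts, -1.44 at Leiden resolution 0.5 and -1.56 with the stricter cell filter. Without the tumor block Folr2, C3 and Acod1 had adjusted p of 0.102, 0.136 and 0.239.

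Heterogeneity among macrophages was compared as each of 6 macrophage-like clusters against the sum of the other 5 in the same tumors. For every cluster but 3 that sum includes cycling cluster 3, so lower cell cycle genes there cannot be told apart from a raised reference. Clusters 1 and 2 held 30.2% ± 6.67 and 29.8% ± 6.88 (SD, n = 6) of macrophage-like cells, cluster 3 held 16.5% ± 3.95, cluster 4 held 15.1% ± 11.3, cluster 10 held 4.28% ± 2.55 and cluster 12 held 4.22% ± 3.99. Mif averaged highest in clusters 10 and 4, at 1306 ± 87.5 and 990 ± 188 CPM, and was called higher in both. Of 160 list tests over the 8 comparisons of classes and clusters, 85 were called and 15 of these held with an estimated correlation. Median, mean and test of a list differed in sign in 20 of the 160, and 1 of these was a called list, the cytokines in cluster 1.

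**Figure D3:**
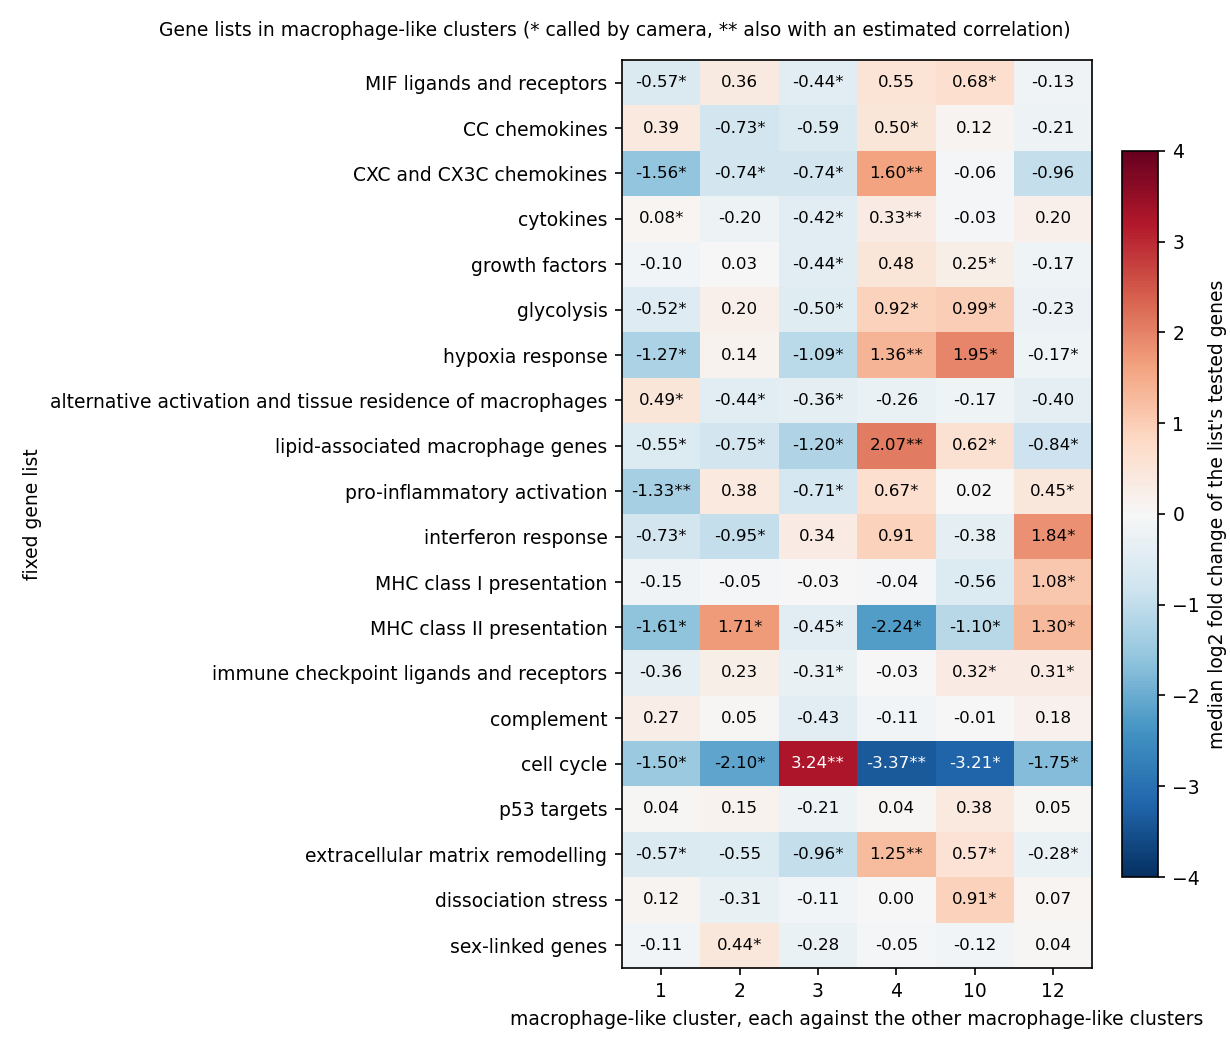
Median log2 fold change of each of 20 gene lists (rows) in each of 6 macrophage-like clusters against the other macrophage-like cells (columns), as a colour scale, with an asterisk where camera called the list and a pair where the call held with an estimated correlation. Cell cycle genes have a median of 3.24 in cluster 3 and -3.37 in cluster 4, whose reference includes cluster 3, and hypoxia genes a median of 1.95 in cluster 10.

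In cluster 1 pro-inflammatory genes were lower and Gas6 was higher. Gas6, a ligand that helps phagocytes take up dying cells, was highest among its printed genes at 131 against 29.6 CPM (log2 fold change 2.10 ± 0.101 SE, edgeR adjusted p = 1.63e-10, 6 of 6 tumors), followed by Cbr2 (2.00), Gpr34 (1.74), the folate receptor Folr2 (1.42) and Ccl12 (1.39). Cell cycle genes were lower in 12 of 20 (Ccnb1 -3.89, Cenpf -3.59; camera adjusted p = 2.99e-41, adjusted p = 0.0549 with an estimated correlation). Pro-inflammatory genes were lower in 6 of 10, with the nitric oxide synthase Nos2 at -4.44 and Il1b at -1.95 (camera adjusted p = 6.62e-11), the list of this cluster whose call held (adjusted p = 0.0175 with an estimated correlation). Hypoxia genes were lower in 6 of 11 (Egln3 -2.01, Slc2a1 -1.49, Vegfa -1.41; camera adjusted p = 9.39e-16) and glycolysis genes in 2 of 16 (camera adjusted p = 1.92e-12), at an adjusted p = 0.0549 and 0.140 with an estimated correlation. MHC class II genes were lower in 5 of 7 (H2-Aa -1.77, Cd74 -1.61; camera adjusted p = 1.23e-06, adjusted p = 0.150 with an estimated correlation). The CXC and CX3C chemokines were lower in 5 of 8 (Cxcl3 -4.46; camera adjusted p = 1.71e-05, adjusted p = 0.0525 with an estimated correlation), and Mmp12 stood at -4.43 among 4 lower and 1 higher of 11 matrix genes (camera adjusted p = 0.0160, adjusted p = 0.222 with an estimated correlation). Lipid-associated genes were lower in 5 of 15 (Gpnmb -3.01; camera adjusted p = 0.00268) and interferon genes in 5 of 16 (camera adjusted p = 0.000626), at an adjusted p = 0.499 and 0.214 with an estimated correlation. Alternative activation genes went up on balance with 3 higher and Arg1 lower (-1.52) of 7 (camera adjusted p = 0.00545, adjusted p = 0.150 with an estimated correlation). The MIF list was lower (camera adjusted p = 0.00393, adjusted p = 0.140 with an estimated correlation), with Cd74 and Ackr3 (-3.38) called, Mif at 467 against 695 CPM (-0.63), Cd44 at -0.51 and Cxcr4 at 0.30. Cytokines had 2 of 9 lower, a median of 0.08, a mean of -0.29 and a camera adjusted p of 0.0322 on the lower side (adjusted p = 0.177 with an estimated correlation). In all 89 genes were higher and 293 lower of 9155. CC chemokines had 3 higher and 4 lower of 10 (camera adjusted p = 0.214). At Leiden resolution 2, where the best match shares a Jaccard index of 0.321 with the cluster, 12 genes were higher, Vegfa stood at 0.025, and Cbr2 (0.99), Gpr34 (0.91), Folr2 (0.80), Ccl12 (0.50), Slc2a1 (-0.71), Egln3 (-0.80) and Arg1 (-0.67) lost their calls. Cd74 stood at -0.91 at Leiden resolution 0.5, Ccl12 at 0.89 with cluster 5 counted as macrophage-like, and on separate UMIs the interferon call was lost (camera adjusted p = 0.366).

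In cluster 2 MHC class II genes were higher in 6 of 7 with a median of 1.71, led by H2-Eb1 (1.83), H2-Aa (1.80) and Cd74 (1.71 ± 0.128 SE, 9849 against 3429 CPM, 6 of 6 tumors) (camera adjusted p = 9.9e-12, adjusted p = 0.0646 with an estimated correlation). The vitamin D receptor Vdr (1.90), Il1b (1.53), the costimulatory ligand Cd80 (1.53), Mgl2 (1.22), the adenosine-making enzyme Nt5e (1.15), Vegfa (1.10) and the cell cycle inhibitor Cdkn1a (1.00) were higher too. Folr2 (-3.31), Cbr2 (-2.94), Gas6 (-2.61), Igf1 (-3.24), Gpnmb (-5.00) and Cd36 (-4.21) were lower. The lipid-associated list was lower in 7 of 15 (camera adjusted p = 6.97e-08, adjusted p = 0.293 with an estimated correlation). Alternative activation genes had 1 higher and 2 lower of 7 (camera adjusted p = 2.58e-06), interferon genes 7 of 15 lower (Rsad2 -2.11; camera adjusted p = 2e-07) and cell cycle genes 13 of 20 lower (Ccna2 -4.36; camera adjusted p = 1.92e-46), each at an adjusted p = 0.0512 with an estimated correlation. CC chemokines were lower in 2 of 10 (Ccl8 -3.45; camera adjusted p = 0.000423) and CXC and CX3C chemokines in 4 of 8 (Cxcl10 -2.10; camera adjusted p = 0.0210), at an adjusted p = 0.0515 and 0.293 with an estimated correlation. The Y-linked Uty (1.12) was higher within a sex-linked list of 4 (camera adjusted p = 0.00200, adjusted p = 0.0646 with an estimated correlation). Mif stood at 686 against 612 CPM (0.24, higher in 5 of 6 tumors) and was not called. Of 9018 genes 90 were higher and 340 lower. At Leiden resolution 2 (Jaccard index 0.389) 4 were higher, Mif stood at -0.13, and Cd74 (0.70), H2-Eb1 (0.64), H2-Aa (0.64), Vdr (0.51), Il1b (0.90), Cd80 (0.62), Nt5e (0.62), Mgl2 (0.91), Uty (0.53), Vegfa (0.32) and Cdkn1a (0.29) lost their calls. Vegfa stood at 0.92 without tumor 3 and 0.86 with the stricter cell filter. Cdkn1a lies on the minimum fold and lost its call without tumor 1 (0.98), tumor 3 (0.96), tumor 5 (0.99), capture 1 (0.98), TMM (0.92) or the filter on low counts (0.99), with the stricter cell filter (0.87) and with cluster 5 counted as macrophage-like (0.90).

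Cluster 3 held the cycling macrophages. Of 20 cell cycle genes, which were kept out of the clustering, 17 were higher with a median of 3.24 (camera adjusted p = 1.3e-94), and the call held (adjusted p = 0.00391 with an estimated correlation). These values describe the cluster and are no independent test. Ccnb1 (5.48) and Ccna2 (5.40), cyclins of mitosis and of DNA replication, led the list, and outside it the spindle motor Kif11 stood at 123 against 1.76 CPM (log2 fold change 6.03 ± 0.094 SE, edgeR adjusted p = 1.4e-17, 6 of 6 tumors) and the mitotic kinase Pbk at 5.76. Ccne1, the cyclin engineered into the transplant, was also higher here, at 41.9 against 8.40 CPM (2.20). Lower by camera were the lipid-associated list in 10 of 15 (Gpnmb -5.20, Cd36 -2.79; camera adjusted p = 1.03e-10), hypoxia genes in 6 of 11 (Egln3 -2.82, Vegfa -1.54; camera adjusted p = 1.03e-07) and matrix genes in 5 of 10 (Ctsk -3.94, Mmp12 -3.49; camera adjusted p = 2.73e-05), at an adjusted p = 0.125, 0.113 and 0.0534 with an estimated correlation. Further lists lower by camera were glycolysis (1 of 16 genes, adjusted p = 1.92e-05), pro-inflammatory genes (3 of 10, 0.000714), growth factors (4 of 13, 0.00218), CXC and CX3C chemokines (3 of 8, with Cxcl3 at -3.93, 0.00933), checkpoint genes (1 of 10, 0.0137), MHC class II genes (0 of 7, 0.0172), the MIF list (1 of 6, 0.0282), cytokines (2 of 10, 0.0290) and alternative activation genes (2 of 7, with Arg1 at -1.95, 0.0388). None of these 9 held, with a lowest adjusted p = 0.108 and a highest of 0.312 with an estimated correlation. Mif stood at 478 against 682 CPM (-0.63) and Cd74 at -0.39, both without a call, and at Leiden resolution 2 (Jaccard index 0.624) Cd74 passed at -1.67. Of 9110 genes 571 were higher and 163 lower.

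Cluster 4 held lipid-associated macrophages with matrix-degrading enzymes. The lipid-associated list was higher in 13 of 15 genes with a median of 2.07 (camera adjusted p = 5.93e-44), led by Gpnmb (5.99 ± 0.115 SE, 674 against 13.2 CPM, 6 of 6 tumors), the fatty acid transporter Cd36 (5.68) and the lipase Lpl (4.48). Mmp12, an elastase of macrophages, stood at 3820 against 115 CPM (5.42), and Ctsk (5.40) and Mmp13 (4.43) joined it in a matrix list with 7 of 10 higher (camera adjusted p = 3.14e-08). Mif was higher at 990 ± 188 against 574 ± 96.2 CPM (log2 fold change 1.10 ± 0.092 SE, edgeR adjusted p = 4.11e-08, 6 of 6 tumors), as was Ackr3 (3.00), while Cd74 was lower (-2.27). MHC class II genes were lower in 6 of 7 (H2-Eb1 -2.73; camera adjusted p = 0.00338, adjusted p = 0.410 with an estimated correlation).

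Of 8 CXC and CX3C chemokines 5 were higher in cluster 4, with Cxcl3 at 6.11 and Cxcl1 at 3.32, and 2 were lower, with Cxcl9 at -3.28 (camera adjusted p = 5.91e-05). The CC chemokines had 3 higher and 2 lower of 10, with Ccl6 at 3.53, Ccl9 at 2.95 and Ccl12 at -2.08 (camera adjusted p = 0.00497, adjusted p = 0.153 with an estimated correlation). Hypoxia genes were higher in 7 of 11 (Egln3 3.02, Ero1l 2.22, Bnip3 1.77; camera adjusted p = 1.84e-12) and glycolysis genes in 7 of 16 (Slc2a1 1.67; camera adjusted p = 4.86e-14, adjusted p = 0.137 with an estimated correlation). Cytokines were higher in 3 of 8 (Il1a 3.30, Il1rn 2.16; camera adjusted p = 0.00101) and pro-inflammatory genes in 4 of 10 (Nos2 4.52; camera adjusted p = 0.00551, adjusted p = 0.197 with an estimated correlation). Arg1 (2.79), Igf1 (3.40), Hbegf (2.39) and the checkpoint ligand Cd274 (2.23) were higher, and Mgl2 (-4.63) was lower. Cell cycle genes were lower in 18 of 20 (Birc5 -4.75, Cenpf -6.18 from 5 counts; camera adjusted p = 8.6e-42). The calls of lipid-associated (adjusted p = 0.0017 with an estimated correlation), matrix (0.0180), CXC and CX3C chemokine (0.0450), cell cycle (0.0455), cytokine and hypoxia lists (each 0.0468) held. Of 8663 genes 459 were higher and 590 lower. Without TMM the median of all genes moved from -0.01 to -0.326, 268 genes were higher and 1041 lower, and Mif stood at 0.785 under the minimum fold.

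Cluster 10 held macrophages with hypoxia and glycolysis genes and the highest Mif of the 6 clusters. Mif stood at 1306 ± 87.5 against 625 ± 49.7 CPM (log2 fold change 1.23 ± 0.091 SE, edgeR adjusted p = 5.36e-17, higher in 5 of 5 tumors), above the 929 ± 167 CPM of sarcoma-like cells in the same 5 tumors. Hypoxia genes were higher in 10 of 11 with a median of 1.95, led by Ndrg1 (2.88 ± 0.127, 354 against 56.1 CPM), the oxygen sensor Egln3 (2.55) and the mitophagy gene Bnip3 (2.38) (camera adjusted p = 5.04e-21, adjusted p = 0.131 with an estimated correlation). Glycolysis genes were higher in 8 of 16, among them the glucose transporter Slc2a1 (2.15), Hk2 (1.62) and Tpi1 (1.29) (camera adjusted p = 8.54e-25, adjusted p = 0.131 with an estimated correlation). Cell cycle genes were lower in 18 of 20 with a median of -3.21 (Mki67 -4.38, Rrm2 -4.51 from 4 counts; camera adjusted p = 6.75e-27, adjusted p = 0.131 with an estimated correlation).

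Dissociation stress genes were higher in 5 of 11 in cluster 10 (Egr1 1.57, Hspa1b 1.52; camera adjusted p = 1.74e-12), MHC class II genes were lower in 4 of 7 (H2-DMb1 -1.51; camera adjusted p = 1.71e-08) and the lipid-associated list had 6 higher, with Fabp5 at 1.99, and 2 lower, with Lpl at -3.24, of 15 (camera adjusted p = 2.64e-06). The MIF list had 2 of 6 higher, Mif and Ackr3 (2.28), with Cd74 at -0.98 (camera adjusted p = 0.0119). Each of these 4 had an adjusted p = 0.131 with an estimated correlation. Growth factors were higher in 4 of 13 (Vegfa 1.21; camera adjusted p = 0.00376), checkpoint genes in 2 of 10 (Cd274 1.84; camera adjusted p = 0.0188) and matrix genes in 2 of 10 (camera adjusted p = 0.0441), at an adjusted p = 0.246, 0.206 and 0.342 with an estimated correlation. Arg1 (1.52) was higher, and Mgl2 (-2.07), Cxcl10 (-2.39) and Ccl7 (-1.41) were lower. Of 8912 genes 211 were higher and 544 lower, in 5 tumors because tumor 5 had 1 cell of the cluster. Without TMM the median of all genes moved from -0.073 to -0.239 and 131 genes were higher and 775 lower, and without capture 1 344 were lower, with Ackr3 at 1.34 (adjusted p = 0.225). With the stricter cell filter the cluster merged into a larger one (Jaccard index 0.211), where Mif stood at 0.30 (adjusted p = 0.203), Ccl7 at 0.24, and 32 genes were higher and 310 lower. Ackr3 (0.93), Slc2a1 (0.72), Hk2 (0.91), Tpi1 (0.38), Vegfa (0.70), Fabp5 (0.23), Arg1 (0.35), Egr1 (0.64), Hspa1b (0.27), Cd274 (0.14) and H2-DMb1 (-0.87) lost their calls there too. With clusters made and genes tested on separate UMIs Mif stood at 0.91, Tpi1 at 0.88, Hspa1b at 0.80 and Ccl7 at -0.59, all under the minimum fold, and the matrix call was lost (camera adjusted p = 0.0771). Hspa1b stood at 0.88 without capture 2 and 0.69 at Leiden resolution 2, where Ccl7 stood at -0.98. Cd74 passed without tumor 2 (-1.08), tumor 6 (-1.04), TMM (-1.13) or the filter on low counts (-1.01), with cluster 6 added (-1.04) and with cluster 5 counted as macrophage-like (-1.03).

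In cluster 12 interferon and antigen presentation genes were higher. Cxcl9, a T cell attractant, stood at 1434 against 56.3 CPM (log2 fold change 5.17 ± 0.418 SE, higher in 4 of 4 tumors) and Cxcl10 at 4.37. Interferon genes were higher in 12 of 16 with a median of 1.84, including Gbp2 (4.16) (camera adjusted p = 2.22e-41, adjusted p = 0.0708 with an estimated correlation). MHC class II genes were higher in 6 of 7 with a median of 1.30 (H2-Eb1 1.5, Cd74 1.30; camera adjusted p = 1.22e-31), and class I genes in 6 of 10 (Nlrc5 1.74, Tap1 1.63; camera adjusted p = 1.98e-29), at an adjusted p = 0.0638 and 0.0708 with an estimated correlation. Pro-inflammatory genes were higher in 2 of 10 (Acod1 2.93, Cd40 2.59; camera adjusted p = 0.000471) and checkpoint ligands in 2 of 11 (Pdcd1lg2 2.29, Cd274 1.96; camera adjusted p = 0.0285), at an adjusted p = 0.105 and 0.540 with an estimated correlation. Ccl5 (2.00) and the complement genes Cfb (2.64) and C3 (1.98) were higher. Lipid-associated genes were lower in 6 of 15 (Gpnmb -4.22, Spp1 -3.08; camera adjusted p = 2.94e-19), cell cycle genes in 11 of 20 (Top2a -3.13; camera adjusted p = 2.41e-36), matrix genes in 3 of 10 (Mmp12 -3.61; camera adjusted p = 0.000153) and hypoxia genes in 1 of 11 (camera adjusted p = 0.00612), at an adjusted p = 0.151, 0.0951, 0.0951 and 0.540 with an estimated correlation. Cxcl3 was lower (-4.78), and Mif stood at -0.15 with no call and at 0.09 without capture 1. Of 8797 genes 104 were higher and 156 lower, in the 4 tumors with enough cells. Adjusted over the list alone, 15 interferon, 3 pro-inflammatory and 3 complement genes were higher, where 12, 2 and 2 were over all genes. Without capture 1 77 genes were lower and without tumor 2 93 were. The cluster has no value on separate UMIs, where its match (Jaccard index 0.362) was named monocyte-like, so these calls were not checked there. Pdcd1lg2 lost its call without tumor 4 (2.36, adjusted p = 0.0960) and Cfb without capture 2 (1.94, adjusted p = 0.0877), and without the tumor block so did Pdcd1lg2 (2.44, adjusted p = 0.0964) and Acod1 (2.56, adjusted p = 0.0608).

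Across the 6 tumors, Mif in sarcoma-like cells was set against 4 measures of the macrophages, to ask whether tumors with more tumor Mif held different macrophages. None of the 4 relations passed. The monocyte-like share of monocyte-like and macrophage-like cells had r = 0.785 (exact permutation p = 0.0542, adjusted p = 0.211) and rho = 0.771 (exact permutation p = 0.103, adjusted p = 0.206), and without the tumors farthest from the median Mif, 1 and 2, r was -0.114, so the relation rests on those tumors. It also rests on which clusters are counted, since r was -0.202 with cluster 5 counted as macrophage-like, which takes tumor 1 from 25.0% to 1.05%, -0.269 with clusters 2 and 4 counted as monocyte-like, and -0.066 without the sarcoma-like clusters 15 and 20. MHC class II genes in macrophage-like cells had r = -0.756 (exact permutation p = 0.106, adjusted p = 0.211) and rho = -0.829 (exact permutation p = 0.0583, adjusted p = 0.206), with r = -0.755 without tumors 1 and 2. The monocyte-like and macrophage-like share of immune-type cells had r = 0.318 (exact permutation p = 0.515, adjusted p = 0.687) and rho = 0.429 (exact permutation p = 0.419, adjusted p = 0.559), with r = 0.179 without them and -0.355 without clusters 15 and 20. Alternative activation genes had r = 0.249 (exact permutation p = 0.697, adjusted p = 0.697) and rho = 0.143 (exact permutation p = 0.803, adjusted p = 0.803), with r = 0.568 without them. Within capture 2 alone the values of r in this order were 0.885, -0.636, 0.556 and 0.274, and within capture 1 alone 0.591, -0.723, 0.185 and 0.097. All p are two-sided.

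**Figure D4:**
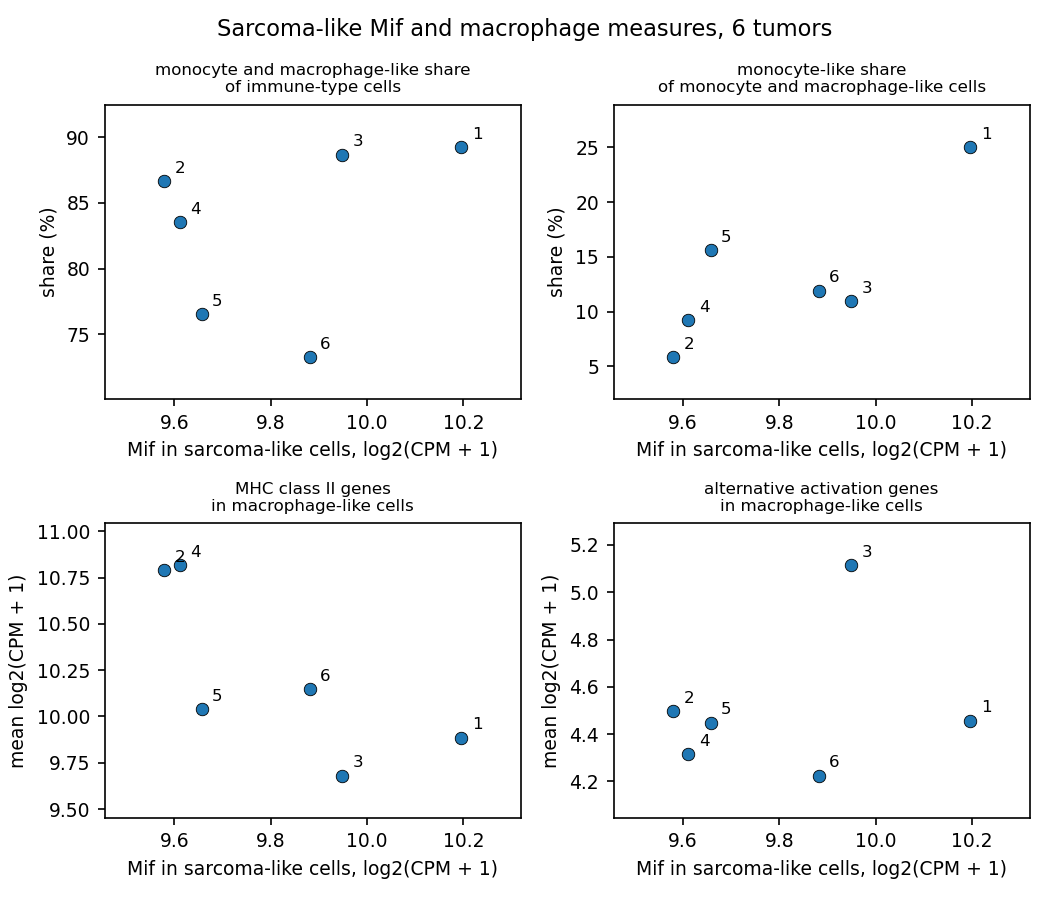
Mif in sarcoma-like cells, in log2(CPM + 1), on the x axis against 4 measures of monocyte-like and macrophage-like cells (shares in %, gene means in log2 CPM), 1 panel each, with 1 numbered point per tumor. Tumor 1 has the highest Mif and the highest monocyte-like share, 25.0%, and r of that panel is -0.114 without tumors 1 and 2.

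The 2 captures took cells of the same pool and serve as a technical control. In sarcoma-like cells 6 of 9062 genes differed between captures: Rpa3 (1.38), Crtc2 (1.5), Fgfrl1 (1.02), Eral1 (1.08) and A4galt (1.23) were higher in capture 1 and Usp50 was lower (-1.23). In monocyte-like and macrophage-like cells 7 of 10222 differed, with Rpa3 (1.24), Cxcl3 (1.00), Ccl24 (1.53), Gm26870 (1.11) and Nckap5l (1.07) higher and S100a9 (-1.38) and Ppbp (-1.23) lower in capture 1. These genes are named because they were called, after their values were seen. The genes with the smallest p had smaller folds, among them Gm10076 (-0.88 in sarcoma-like and -0.91 in the other cells) and the ribosomal genes Rps29 (-0.48 and -0.43) and Rpl35 (-0.46 and -0.44). DESeq2 called 0 genes in sarcoma-like cells, and 3 higher and 1 lower in the other cells. In edgeR 870 of 9062 genes had an unadjusted p under 0.05 in sarcoma-like cells, and 1722 of 10222 in the other cells. Without the tumor block 3 and 0 genes were called in sarcoma-like cells and 1 and 0 in the other cells. Shares of 11 classes had exact adjusted p from 0.945 to 1.0 between captures, and over 11 tests 1 class alone could not pass with 6 tumors. The largest differences were neutrophil-like cells, at -0.310 percentage points in capture 1 minus capture 2 (lower in 5 of 6 tumors, exact two-sided p = 0.281), and T-like cells, at 0.310 (higher in 4 of 6 tumors, exact two-sided p = 0.313).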

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

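The 3 patterns weighed here are Mif in macrophage-like cluster 10, the scarcity of sex-linked RNA in sarcoma-like cells, and a shift of 2 whole chromosomes in sarcoma-like cells. The tests of sarcoma RNA in cluster 10, of scaling, of the number of Ddx3y counts and of free Y-linked RNA were chosen after the result was seen. The other tests were written down before their values were computed, although the chromosome pattern was itself found in the data.

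Mif stood at 1306 ± 87.5 CPM in cluster 10, above other macrophage-like cells (625 ± 49.7) and sarcoma-like cells (929 ± 167) in the same 5 tumors. Carry-over of sarcoma RNA is unlikely to account for this, since sarcoma markers in cluster 10 had a median of 0.946% of their sarcoma-like level, against 0.518% in other macrophage-like cells, and scaling alone does not remove the rise, which was 1.08 without TMM. A biological hypothesis is that Mif RNA goes with the response to low oxygen in any cell of these tumors, which could place it in hypoxic regions. Within sarcoma-like cells, thinned to 3000 UMIs, Mif and the hypoxia genes had a mean rho of 0.213 (range 0.013 to 0.462, positive in 6 of 6 tumors, exact two-sided p = 0.03125), and within macrophage-like cells outside clusters 4 and 10 a mean rho of 0.314 (range 0.135 to 0.385, positive in 6 of 6 tumors), each above 100% of 1000 random lists. These lists matched expression and not how genes vary together, so other sets of co-varying genes might exceed them too. Cells of several clusters were ranked together, so rho can repeat differences between clusters. Clusters 1 and 3 had both lower Mif and lower hypoxia genes. Mif stood at 1721 CPM in sarcoma-like cluster 15 and at 809 CPM in the other sarcoma-like clusters. Oxygen was not measured, and under the stricter cell filter, where the cluster merged into a larger one (Jaccard index 0.211), Mif stood at 0.30 in that one.

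Sarcoma-like cells held Y-linked RNA far under the level of the host's macrophage-like cells and 3 counts of Xist. Too few counts is an unlikely explanation, since 1.06% of the 2356 Ddx3y counts expected at the macrophage-like level were seen. The few Y-linked counts may be free RNA of host cells, since their sum lay at 1.10% of the macrophage-like level and 12 macrophage markers lay at 0.608% to 23.8%, with a median of 0.851%. Mertk alone sets the upper end of that range, and the next highest marker, Cd68, lay at 1.18%. A female donor without Xist, or a male donor that lost its Y chromosome, could each leave this pattern. A test for 2 active X chromosomes could not decide, with X-linked minus autosomal genes at a median of 0.165 (interval 0.042 to 0.353).

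Genes on chromosomes 3 and 15 had median log2 fold changes 0.598 and 0.593 above that of autosomal genes in sarcoma-like against monocyte-like and macrophage-like cells, with the next chromosome, 8, at 0.321. A difference between mesenchymal and myeloid cells is unlikely to explain it, since against host fibroblast-like cells the shifts were 0.530 (interval 0.419 to 0.609) and 0.515 (interval 0.429 to 0.663), with other chromosomes between -0.352 and 0.274. Nor is it a matter of a few regions, since 20 of 20 stretches of the 2 chromosomes lay above the autosomal median, where the highest other chromosome had 8 of 10. A biological hypothesis is an extra copy of both chromosomes in the transplanted cells, for which 3 copies against 2 would give 0.585, and each tumor had a shift near it, at 0.564 ± 0.074 and 0.582 ± 0.034 (SD, n = 6). DNA was not measured, and the fibroblast-like reference is 30 cells, whose Y-linked RNA stood at 130 CPM.

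The sums of each tumor were also regrouped and tested again. For the captures in monocyte-like and macrophage-like cells chance can be excluded only against groupings that part every tumor's 2 sums, where 1 of 32, the real one, gave as many as 7 genes (highest other 1). That is the smallest share 32 groupings allow. Of 68 drawn groupings that part fewer tumors 15 called genes and 1 reached 7, and the real grouping called 1 gene without the tumor block and 4 with DESeq2. For the captures in sarcoma-like cells chance cannot be excluded, where 5 of 32 groupings gave at least the real 6 genes and the highest gave 13, and 14 of 68 drawn ones called genes, at most 11. For classes and clusters regrouping is no test of chance, because they were made from the RNA of the same cells, and only the values are given. The real grouping alone, 1 of 32, gave as many genes for sarcoma-like against monocyte-like and macrophage-like cells (4209 genes, highest other 0), monocyte-like against macrophage-like cells (449, 0), cluster 1 (382, 0), cluster 2 (430, 0), cluster 3 (734, 0) and cluster 4 (1049, 1). Fewer groupings exist for cluster 10 (755 genes, 16 groupings, highest other 25) and cluster 12 (260 genes, 8 groupings, highest other 0).

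Of 295 values tested for 1 tumor far from the others, over 6 tumors or over the 5 and 4 of clusters 10 and 12, 24 had one, where chance alone gives about 1 in 20 groups. Tumor 5 had the highest endothelial-like share, which is cluster 21, at 0.756% (others 0.0815% to 0.204%). Tumor 1 had the highest share of cluster 5, at 18.2% (others 3.81% to 6.76%), and of the sarcoma-like cluster 15, at 5.70% (others 0.0812% to 0.815%). Mif in monocyte-like cells was lowest in tumor 5, at 280 CPM (others 497 to 580), and alternative activation genes in macrophage-like cells were highest in tumor 3, at a mean log2 of 5.11 (others 4.22 to 4.50).

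Log2 differences of named genes stood apart in single tumors as follows. At few counts, as for Cenpf in cluster 4, a value can rest on a tumor with no counts. In sarcoma-like against monocyte-like and macrophage-like cells, tumor 5 had Cxcr4 at -7.62 (others -5.70 to -4.88) and Arg1 at -5.39 (others -8.67 to -7.74). In monocyte-like against macrophage-like cells, tumor 2 had Cxcl10 at 1.97 (others 3.36 to 4.01), and tumor 5 had Pf4 at -3.31 (others -1.77 to -1.02) and Mmp12 at -6.42 (others -3.20 to -2.02). In cluster 1, Mmp12 was -7.26 in tumor 5 (others -4.60 to -3.52) and Gpnmb -1.21 in tumor 4 (others -3.5 to -2.85). In cluster 2, Mgl2 was 2.12 in tumor 5 (others 0.73 to 1.16) and Uty 0.61 in tumor 3 (others 1.01 to 1.20). In cluster 3, Egln3 was -4.92 in tumor 5 (others -2.96 to -1.79). In cluster 4, Cxcl9 was -6.30 in tumor 2 (others -3.66 to -2.34), Birc5 -7.37 in tumor 3 (others -5.20 to -4.25) and Cenpf -3.20 in tumor 4 (others -6.58 to -5.45). In cluster 10, Egr1 was 2.28 in tumor 2 (others 0.97 to 1.20) and Mki67 -1.76 in tumor 4 (others -4.82 to -4.47). In cluster 12, Nlrc5 was 2.79 in tumor 3 (others 1.23 to 1.39), and tumor 5 had Cd40 at 3.86 (others 1.91 to 2.16) and Top2a at -7.45 (others -3.42 to -2.81).

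Data that no comparison used also held a signal. Hashtag 1, which belongs to no called mouse, led 1243 barcodes that pass the cell filter with at least 90% of their hashtag UMIs, of 1541 that it led in all. Antibody counts, as median UMIs per cell, were 1099 for CD11b in neutrophil-like and 1094 in macrophage-like cells (sarcoma-like 8), and 88 for F4/80 in macrophage-like and 37 in monocyte-like cells (sarcoma-like 1). CD4 stood at 119 and CD3 at 23 in T-like cells (sarcoma-like 0).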

How the results depend on the processing

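Under the alternatives chosen before the data were examined 3216 values of single genes kept their direction and their side of the threshold, 73 were weaker, 11 stronger and 12 reversed. Of class tests 255 kept both, 50 were weaker and 6 reversed, and 239 counts of genes stayed within 1.5 times while 53 moved. Of list results 364 kept both, 89 were weaker, 11 stronger and 9 reversed, and 10 counts of lists moved. Of shares 49 stayed within 1 SD and 1 moved. Cluster 5 counted as macrophage-like, clusters 2 and 4 counted as monocyte-like, clusters 15 and 20 left out, cluster 6 added to the macrophage-like cells, sarcoma-like clusters 7 or 9 alone, 1 tumor left out of the class tests, and cells without the highest Scrublet scores were alternatives chosen after seeing the data. Scrublet's own calls were not used because its threshold did not work. Cluster 10 has no value without the highest Scrublet scores or at Leiden resolution 0.5, where no cluster matched it. Cluster 12 has none at Leiden resolution 0.5, where no cluster matched it, or on separate UMIs, where its match was named monocyte-like. Small clusters and shallow cells limit the rest: cluster 10 has 205 cells, cluster 12 has 190, and the median neutrophil-like cell has 1457 UMIs.

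Without a minimum fold more genes pass by construction: 4122 higher and 4059 lower for sarcoma-like cells, 1096 and 1041 for monocyte-like cells, 1680 and 1518 for cluster 1, 1468 and 1499 for cluster 2, 2478 and 2043 for cluster 3, 1786 and 1904 for cluster 4, 904 and 1361 for cluster 10, 300 and 274 for cluster 12, and between captures 51 and 33 in sarcoma-like and 386 and 204 in the other cells. Counting the clustering genes too gave 325 higher for monocyte-like cells, 461 lower for cluster 1, 178 higher for cluster 2, 276 lower for cluster 3, 321 higher for cluster 10 and 184 higher for cluster 12. Without the filter on low counts more genes were tested, with 523 lower for cluster 2, 298 lower for cluster 3, and between captures 9 and 11 in sarcoma-like and 14 and 6 in the other cells.

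For the following changes the cause was not tested. Without TMM cluster 4 had 268 higher and 1041 lower and cluster 10 had 131 higher. DESeq2 gave 93 lower for cluster 12, and between captures 0 and 0 in sarcoma-like and 3 and 1 in the other cells. Without the tumor as replicate block the captures gave 3 and 0, and 1 and 0, and cluster 3 had 8 lists called. List calls lost without the block were the interferon response (adjusted p = 0.180) and MHC class I (0.153) in sarcoma-like cells, CC chemokines (0.385) and MHC class II (0.139) in monocyte-like cells, cytokines (0.484) and matrix (0.0814) in cluster 1, CXC and CX3C chemokines (0.0671) in cluster 2, MIF genes (0.0818), cytokines (0.182), alternative activation (0.161), MHC class II (0.182) and checkpoint genes (0.0818) in cluster 3, CC chemokines (0.137), cytokines (0.110) and pro-inflammatory genes (0.0684) in cluster 4, and matrix (0.0954) in cluster 10. Pro-inflammatory genes in cluster 2 (0.0304) and MHC class I in cluster 10 (0.0403) passed without it. Apart from the captures and 5 gene calls given with their comparisons (Folr2, C3 and Acod1 in monocyte-like cells, Pdcd1lg2 and Acod1 in cluster 12), the block changed no other call of a printed gene or of a list between classes and clusters, and other counts of genes stayed within 1.5 times, such as 163 higher and 249 lower for monocyte-like cells and 93 and 118 for cluster 12. On separate UMIs cluster 10 had 102 higher, cluster 2 had 14 lists called, and Ddt in sarcoma-like against T-like cells was -0.18. Lists with no call on either side also changed direction: on separate UMIs CXC and CX3C chemokines in monocyte-like cells (camera adjusted p = 0.355) and cluster 10 (0.841), MHC class I in clusters 2 (0.616) and 3 (0.760), dissociation stress in cluster 4 (0.689) and sex-linked genes in cluster 10 (0.574), and without the block MHC class I in clusters 2 (0.967) and 3 (0.790) and the interferon response in cluster 3 (0.988). At Leiden resolution 2 cluster 1 had 12 higher and cluster 2 had 4, the monocyte-like share was 16.2%, and these values reversed: in monocyte-like cells Mif 0.38, Ackr3 1.64, Cxcl3 3.70, Cd36 0.39, Spp1 0.70 and Mmp12 0.53, Vegfa 0.025 in cluster 1, and Mif -0.13 in cluster 2 and 0.04 in cluster 12. The stricter cell filter gave 140 higher for cluster 1, 32 higher and 310 lower for cluster 10, Ccl7 at 0.24 there, and capture differences in share of -0.714 (macrophage-like), 0.0132 (monocyte-like), 0.175 (sarcoma-like) and 0.5005 (unnamed) percentage points.

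With cluster 5 counted as macrophage-like, the monocyte-like class is a different set of cells, and its genes were tested in 5 tumors. It had 731 genes lower, 7 lists called, and Ddt -0.37, Cd74 -0.165, Ifit3 -2.91, Ifit1 -1.98, Ifit2 -1.87, Rsad2 -1.41, Oasl1 -0.56, Ccl5 -0.50, Ccl12 -2.91, Cxcl10 -1.18, Il15 -2.58 and Cd40 -0.85. Lists turned to the lower side for interferon (camera adjusted p = 0.376), CC chemokines (0.144) and MHC class II (0.148) and to the higher for glycolysis (0.0737), hypoxia (0.572) and matrix (0.617). The shares were 72.6% macrophage-like and 1.86% monocyte-like, and Mif and Cd74 in sarcoma-like against macrophage-like cells were 0.526 and -6.47. With clusters 2 and 4 counted as monocyte-like, also other cells by construction, the shares were 35.7% macrophage-like and 38.7% monocyte-like, Mif 0.66, Ackr3 2.18, Ccl12 -0.49, Cxcl3 4.33, Il18 -0.038, Igf1 0.83, Cd36 3.23, Ctsl 1.46, Spp1 2.73, Tap1 -0.043 and Mmp12 3.57 reversed, and the lipid-associated list turned to the higher side (camera adjusted p = 4.5e-08). So did CXC and CX3C chemokines (0.00123), glycolysis (2.8e-07), hypoxia (4.22e-06), matrix (0.00117) and growth factors (0.379), none of them called before. The comparisons of macrophage-like clusters were not run with it. Across tumors, r of Mif with the monocyte-like share was -0.202 with cluster 5 counted as macrophage-like, -0.269 with clusters 2 and 4 counted as monocyte-like and -0.066 without clusters 15 and 20, and r with the monocyte-like and macrophage-like share was -0.355 without clusters 15 and 20. With cluster 7 alone as the sarcoma-like class Mif against macrophage-like cells was 0.042, and Ddt was -0.073 against macrophage-like, -0.047 against monocyte-like and -0.178 against T-like cells. An estimated correlation left 0 of 12 lists for sarcoma-like cells, 7 of 11 for monocyte-like cells, 1 of 12 for cluster 1, 0 of 8 for cluster 2, 1 of 13 for cluster 3, 6 of 10 for cluster 4, 0 of 10 for cluster 10 and 0 of 9 for cluster 12.

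Leaving out 1 tumor or 1 capture gave ranges of 344 to 567 genes lower for cluster 10, 77 to 179 lower for cluster 12, -0.024 to 0.24 for Ddt in monocyte-like cells, -0.37 to 0.086 for Mif in cluster 12, and in sarcoma-like cells 0.414 to 0.575 for Mif and -7.30 to -5.97 for Cd74 against macrophage-like cells and -0.321 to 0.042 for Ddt against dendritic-like cells. Fewer tumors or cells are part of that construction.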

Other observations

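The 1243 barcodes led by hashtag 1 given above included cells with macrophage RNA. Their median was 10869 UMIs, with C1qa at 3459, Csf1r at 501, Cd74 at 6561, Mif at 465, Col1a1 at 203 and Ddx3y at 70.6 CPM. Their antibody medians were 1018 UMIs for CD11b and 88 for F4/80. Their tumor of origin is not given, and they were not analysed here.

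Cluster 15, a sarcoma-like cluster led by Col18a1, Timp3 and Clu, had 86 of its 104 cells in tumor 1. Mif stood at 1721 CPM in it and at 809 CPM in the other 584 sarcoma-like cells. Its summed Y-linked RNA stood at 2.61 CPM against 2.04 CPM in those cells.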
